A study of Escherichia coli with 6 samples.

How the data were processed

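RNA was measured in 6 libraries of wild-type Escherichia coli K-12 W3110, a laboratory strain. Cells were grown in M63, a minimal salts medium, with 0.4% glucose to an optical density at 600 nm of 0.3. The nickel group of 3 libraries received 50 µM NiCl2 for 10 min before freezing, and the control group of 3 libraries received none. Per the labels' protocols, total RNA was extracted with acid phenol, treated with DNase and depleted before strand-oriented libraries were made with a ScriptSeq kit. Groups and replicate numbers were taken from the labels. The labels do not state that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

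The authors deposited a table of FPKM values (fragments scaled by feature length and by mapped total), with a coverage value beside each FPKM value, for 4440 annotated features of the W3110 chromosome. Per the submitters' processing notes, CASAVA 1.8.2 and Cufflinks 2.0.2 were used. The aligner, the annotation version and the strand setting of the counting are not given in the sources used here. The deposited FPKM and coverage values stood in 1 fixed ratio within each library, which speaks against changes made gene by gene to FPKM alone. It does not show whether a scaling factor per library was applied, and this is left open. The deposited coverage is the mean depth of reads over a feature and was used only to estimate reads. With 50-base reads and fragments of mean length 200 and SD 80 bases, 98.98% of 3533 low values came within 0.1 of a whole number of reads when the shortest fragment was set to 45 bases. The read length and shortest fragment were thus inferred from the values. The fragment mean and SD were taken as the defaults of Cufflinks and were not varied. The estimated reads in features were 12.1, 11.1 and 11.5 M (mega-reads) in control replicates 1, 2 and 3 and 11.9, 10.1 and 11.2 M in nickel replicates 1, 2 and 3. Because FPKM divides by an effective length, 1 read was worth 116.4 to 139.6 FPKM in a feature of 76 bases, 0.619 to 0.743 in one of 300 bases and 0.0778 to 0.0934 in one of 1000 bases. Levels of short RNAs are therefore coarse, and 245 features were shorter than 200 bases.

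Positions are those of the deposited table, on the W3110 chromosome and counted from 1. Symbols were updated from a reference gene table of another K-12 strain, MG1655 (assembly ASM584v2), which was used for names only. It matched 4289 features and renamed 631. A further 34 features had no name, 73 features shared 11 symbols, and 167 features were at 0 in all 6 libraries. The table gives no strand, so values of overlapping genes, of antisense partners and of near-identical copies such as the rRNA genes are uncertain. Many named genes overlap a neighbour by a few bases, and overlaps of more than 10 bases are given in the report.

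Values were analysed as log2(FPKM + 1), with a pseudocount of 1, for genes with a mean FPKM of at least 1. This scale understates the change of low genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with group as the only term. Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used of called genes. All adjusted p-values are from limma. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

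Before the data were examined, 36 gene lists with 773 genes were fixed from textbook knowledge of E. coli, together with the tests and most of the alternatives. Of the listed genes, 16 had no match in the table. Lists with at least 4 tested genes were compared with all other genes by limma's camera, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists, and again with a correlation estimated from the residuals. Each list median was also set against 10000 random lists of the same size matched on mean expression. Fry, which tests whether the genes of a list move without comparing them with other genes, was run beside it. The lists overlap, so that a gene may count in several. A further 8 lists were chosen after the values were seen and stand apart.

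Named genes follow a rule fixed at the same time: every tested gene of the nickel and cobalt list; the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap; and up to 4 members per list with the smallest p. A further 88 genes were named after their values were seen, because they make up a small count or are well known members of a list.

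The code was tested on simulated data. In 4206 simulated genes with the real means and spreads, limma recovered 43.3% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 7 false calls (4.43% of the calls). In 5 runs without changed genes there were 0 calls. Camera called the 1 list shifted in the simulation and 0 of the others. The simulated noise was drawn independently for each gene. The run thus does not test camera on lists whose genes vary together, such as general stress (estimated correlation 0.83). Changed genes were drawn only above a minimum mean level, so the recovery of low genes was not tested. They were a small part of the 4206 genes and went up and down about equally. In the data 77.1% of the genes tested were called. The recovery and the share of false calls therefore do not carry over to the data.

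Alternatives were pseudocounts of 0.1 and 10, no filter or a mean FPKM of at least 10, median-of-ratios scaling, quantile normalization, FPKM rescaled to an equal total per library, no mean-variance trend, array weights, the replicate number as a block, and each library left out in turn. After the data were seen, 4 more were added: limma-voom on the estimated reads, features of at least 200 bases, a mean of at least 10 estimated reads, and leaving out both libraries numbered 1. The filter at a mean FPKM of at least 10 also removes members with low levels from the lists, so that lists then hold fewer genes. Rescaling to an equal total also made all values smaller, so that the pseudocount of 1 weighed more there. A count test was planned for the case that whole read counts were at hand, and was not run because the deposited unit is FPKM.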

Results

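The transcriptome of E. coli W3110 was compared between cells exposed to nickel for 10 min and untreated cells, a question of how the cells respond when nickel overloads them. There were 3 libraries per group, with 10.1 to 12.1 M estimated reads in features per library. Correlations of log2(FPKM + 1) across genes were 0.981 to 0.987 between libraries of the same group and 0.875 to 0.908 between groups. Libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom of 18.4 to 61.0, which does not show whether they came from separate cultures. The 10 most abundant features took 14.8% to 15.9% of the reads in control and 21.9% to 22.5% in nickel. The 6S RNA gene ssrS alone made up 10.1% to 14.4% of the summed FPKM in control and 25.3% to 32.4% in nickel. Remaining rRNA took 0.00385% to 0.0225% of the reads, with the highest share in control replicate 1.

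The nickel and cobalt efflux gene rcnA (yohM in the deposited table; W3110 chromosome, 2189251 to 2190075, a coding gene), which the labels name as the internal control of the exposure, rose 26.2-fold. Because rcnA was used to choose the nickel dose and time, its rise follows from the choice of exposure and serves as a check of the labels. Its FPKM was 14.8 ± 1.44 (SD, n = 3) in control and 411 ± 16.5 (SD, n = 3) in nickel, and all 3 nickel libraries lay above all 3 control libraries. The log2 fold change was 4.71 (SE 0.0962; limma adjusted p = 4.18e-07). An exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Next to it, the repressor gene rcnR (yohL; 2188858 to 2189130) rose by a log2 of 3.37, from 213 ± 14.5 to 2224 ± 254 FPKM (SD, n = 3), and rcnB (yohN; 2190294 to 2190632), which encodes a periplasmic protein of the same system, rose by 2.07.

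The genes of the nickel importer, nikABCDE, had low levels, with group means of 0.997 to 6.31 FPKM and 15.5 (nikC) to 47.3 (nikA) estimated reads per library on average. The substrate-binding protein gene nikA and the permease gene nikC fell, by 0.69 each on the log2 scale (adjusted p = 0.00661 and 0.00892 by limma). At the other end of the same operon nikE rose by 0.84 (adjusted p = 0.00122 by limma). The repressor gene nikR rose by 0.81, and this call was lost under median-of-ratios scaling (log2 0.47, adjusted p = 0.0572; range over all alternatives 6.95e-04 to 0.0572). The change of nikB was -0.41 and did not pass (adjusted p = 0.0966 by limma). It passed without control replicate 3 (-0.56) and under median-of-ratios scaling (-0.63) and quantile normalization (-0.71), and over all alternatives nikB ran from -0.71 to -0.10 (adjusted p = 0.00785 to 0.444). The change of nikD was 0.07, and its sign turned under median-of-ratios scaling (-0.21), quantile normalization (-0.27) and array weights (-0.06), and without control replicate 1 (-0.25) or nickel replicate 3 (-0.09). Neighbouring nik genes overlap by 1 to 5 bases. As a list of 9 genes, nickel and cobalt homeostasis had 5 rises, 2 falls and 2 genes that did not pass, and camera did not call it (adjusted p = 0.520). A filter at a mean FPKM of at least 10 removes the 5 importer genes, and only rcnA, rcnB, rcnR and nikR then remain; those 4 were called (adjusted p = 0.0442). The range over all alternatives with the preset correlation, this one included, was 0.0442 to 0.657. With an estimated correlation camera did not call the list of 9 genes (adjusted p = 0.680).

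**Figure D1:**
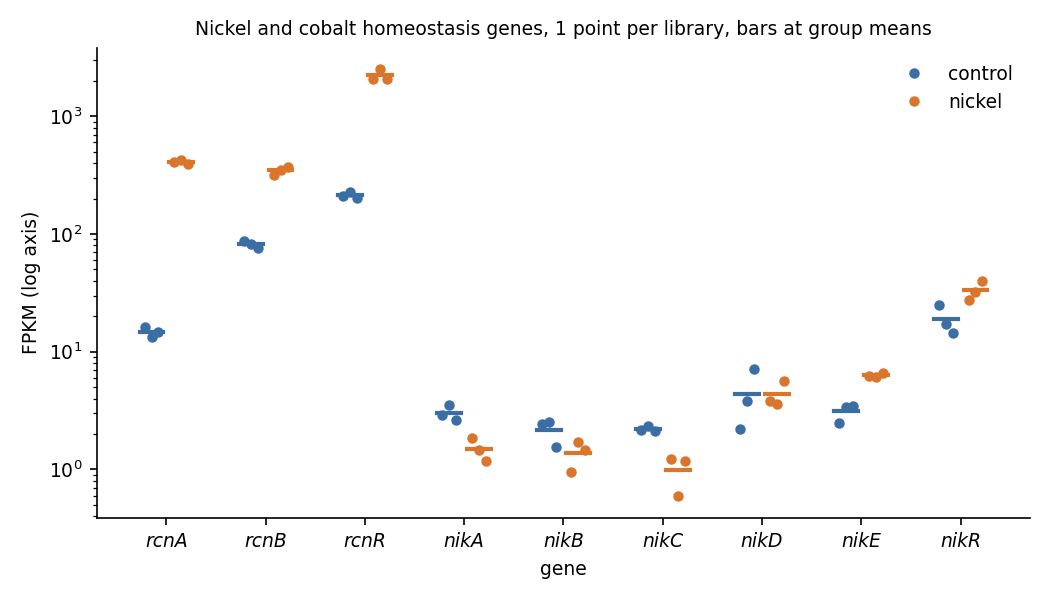
FPKM (log axis) of the 9 nickel and cobalt homeostasis genes in each of the 3 control and 3 nickel libraries; bars mark the group means. For rcnA the mean was 14.8 in control and 411 in nickel, while the nikABCDE means stayed at or under 6.31.

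Across the transcriptome, 3244 of 4206 genes tested (77.1%) were called by limma, of which 2072 rose and 1172 fell. At least 2-fold changes were called in 1588 genes, 947 upward and 641 downward. The groups did not overlap in 3352 genes (79.7%, against 10% by chance). The split between rises and falls depended on scaling. The median log2 fold change of all genes was 0.34 with FPKM as deposited, 0.25 after rescaling to equal totals, 0.14 after quantile normalization and 0.02 after median-of-ratios scaling, and under the last of these 1487 genes rose and 1523 fell. Small changes below these medians are thus relative to the scaling chosen. The value of 0.25 does not come from scaling alone. Summed FPKM was 4.40e+06 to 4.65e+06 in control and 4.23e+06 to 4.77e+06 in nickel, so equal totals moved the groups little against each other. Rescaling also made all values smaller, so that the pseudocount of 1 weighed more. With FPKM as deposited and a pseudocount of 10 the median was 0.19.

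**Figure D2:**
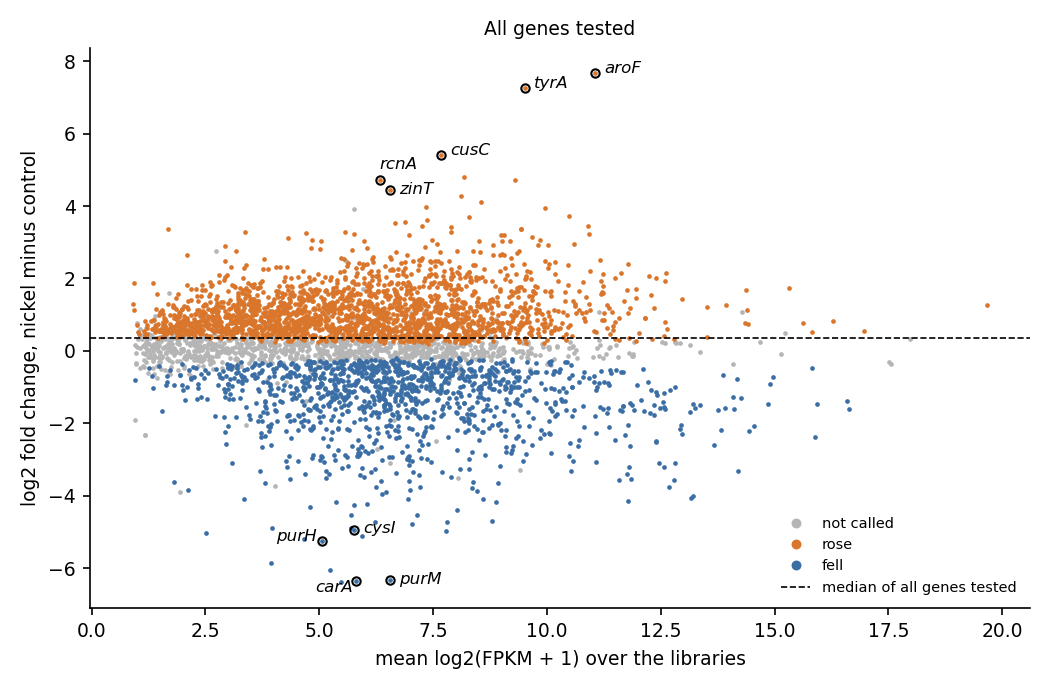
Log2 fold change (nickel minus control) against mean log2(FPKM + 1) over the 6 libraries for the 4206 genes tested, coloured by whether the gene rose, fell or was not called; the dashed line marks the median of 0.34. Some genes with large changes are named. Among those named, aroF (7.67) and tyrA (7.25) are highest and carA (-6.37) and purM (-6.33) lowest. The small RNA gene rybB, which rested on few reads, lies slightly below carA and is not named.

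The largest rises were those of aroF and tyrA, adjacent genes that encode a first enzyme of aromatic amino acid synthesis and an enzyme of tyrosine synthesis. The FPKM of aroF (2738736 to 2739806) went from 150 ± 16.5 to 30491 ± 599 (SD, n = 3), a log2 of 7.67 (SE 0.103; limma adjusted p = 9.21e-08) and a 203-fold rise. That of tyrA (2737604 to 2738725) went from 58.3 ± 6.81 to 9051 ± 1189 (SD, n = 3), a log2 of 7.25 (SE 0.132; limma adjusted p = 2.55e-07). The nearby yfiL (2740016 to 2740381) rose by 4.27. Among genes of metal handling, cusC and cusF of the copper and silver efflux system rose by 5.41 and 3.93, and zinT (yodA), a periplasmic zinc-binding protein gene, rose by 4.44. The remaining large rises were psiE (yjbA) at 4.80, yibT at 4.71, ycgB at 4.10, pliG (ycgK) at 3.98 and dps, which encodes a DNA-binding ferritin-like protein, at 3.73.

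The largest falls were dominated by nucleotide synthesis. The FPKM of purM (2619853 to 2620890) went from 840 ± 93.8 to 9.52 ± 1.84 (SD, n = 3), a log2 of -6.33 (SE 0.156; limma adjusted p = 6.30e-07). Other purine genes among the 12 largest falls were purK (-6.04), purE (-5.87), purH (-5.24) and purL (-5.10), and purE and purK overlap by 4 bases. Both genes of carbamoyl phosphate synthetase fell, carA (29651 to 30799) by 6.37 and carB by 4.90 on the log2 scale. Further falls were those of yedN (-5.20), the sulfite reductase gene cysI (-4.94) and rnpA (-4.99), the protein of RNase P, which overlaps yidD by 37 bases. The small RNA genes rybB (79 bases) and oxyS (110 bases) had log2 fold changes of -6.39 and -4.88, but these rested on few reads and their size was not fixed. Over all alternatives the log2 fold change ran from -8.68 to -2.67 for rybB and from -7.09 to -2.54 for oxyS. Leaving out nickel replicate 2 moved rybB to -8.68, and leaving out nickel replicate 1 or 3 moved it to -5.25. Leaving out nickel replicate 3 moved oxyS to -6.41, and leaving out nickel replicate 1 or 2 moved it to -4.11. Estimated reads of rybB were 6, 6 and 2 in control and 0, 1 and 0 in nickel, and those of oxyS were 4, 2 and 7 in control and 0, 0 and 1 in nickel. Without both libraries numbered 1 neither passed (rybB -5.01, adjusted p = 0.0909; oxyS -4.11, adjusted p = 0.0578). With array weights rybB also did not pass (-4.08, adjusted p = 0.0674). Over all alternatives the adjusted p ranged from 5.13e-05 to 0.0909 for rybB and from 8.81e-05 to 0.0578 for oxyS.

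Camera with the preset correlation called 13 of the 36 lists, 3 upward and 10 downward. With an estimated correlation it called 0 (lowest adjusted p = 0.413), so calls of lists hold only with the preset correlation. The loss does not come from the size of the correlation alone. For the tricarboxylic acid cycle the estimate was 0.012, near the preset 0.01, yet camera's unadjusted p went from 0.186 to 0.263. For ribosomal proteins, where all 54 genes fell, camera's unadjusted p with an estimated correlation was 0.0275. With so few libraries, 0 calls in that setting do not speak against a single list. Fry called 29 lists in one direction and 36 in either direction. It does not compare a list with other genes. As 77.1% of all genes tested were called, the calls by fry do not single out these lists. The counts adjusted over the list alone equalled those over all genes in 33 of the 36 lists, and the other 3 are given with both. Among the called lists, the medians of zinc homeostasis (percentile 96.1), hydrogenases (92.7) and sigma E (11.2) lay within the central 95% of random lists matched on expression. Among the lists not called, those of aromatic amino acid synthesis (99.7), acid resistance (99.2) and copper and silver homeostasis (99.1) lay above it. The random lists were drawn gene by gene and take no account of genes that vary together. Each list is given with the preset adjusted p first. Reads may be shared where named genes overlap their neighbours by more than 10 bases in all, as in cysA (11), cysW and hycH (12 each), mmuM and mmuP (14 each), oxyR (18), nrdE (28), sufD (30), nrdI and lptA (32 each), and their values are uncertain to that extent.

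**Figure D3:**
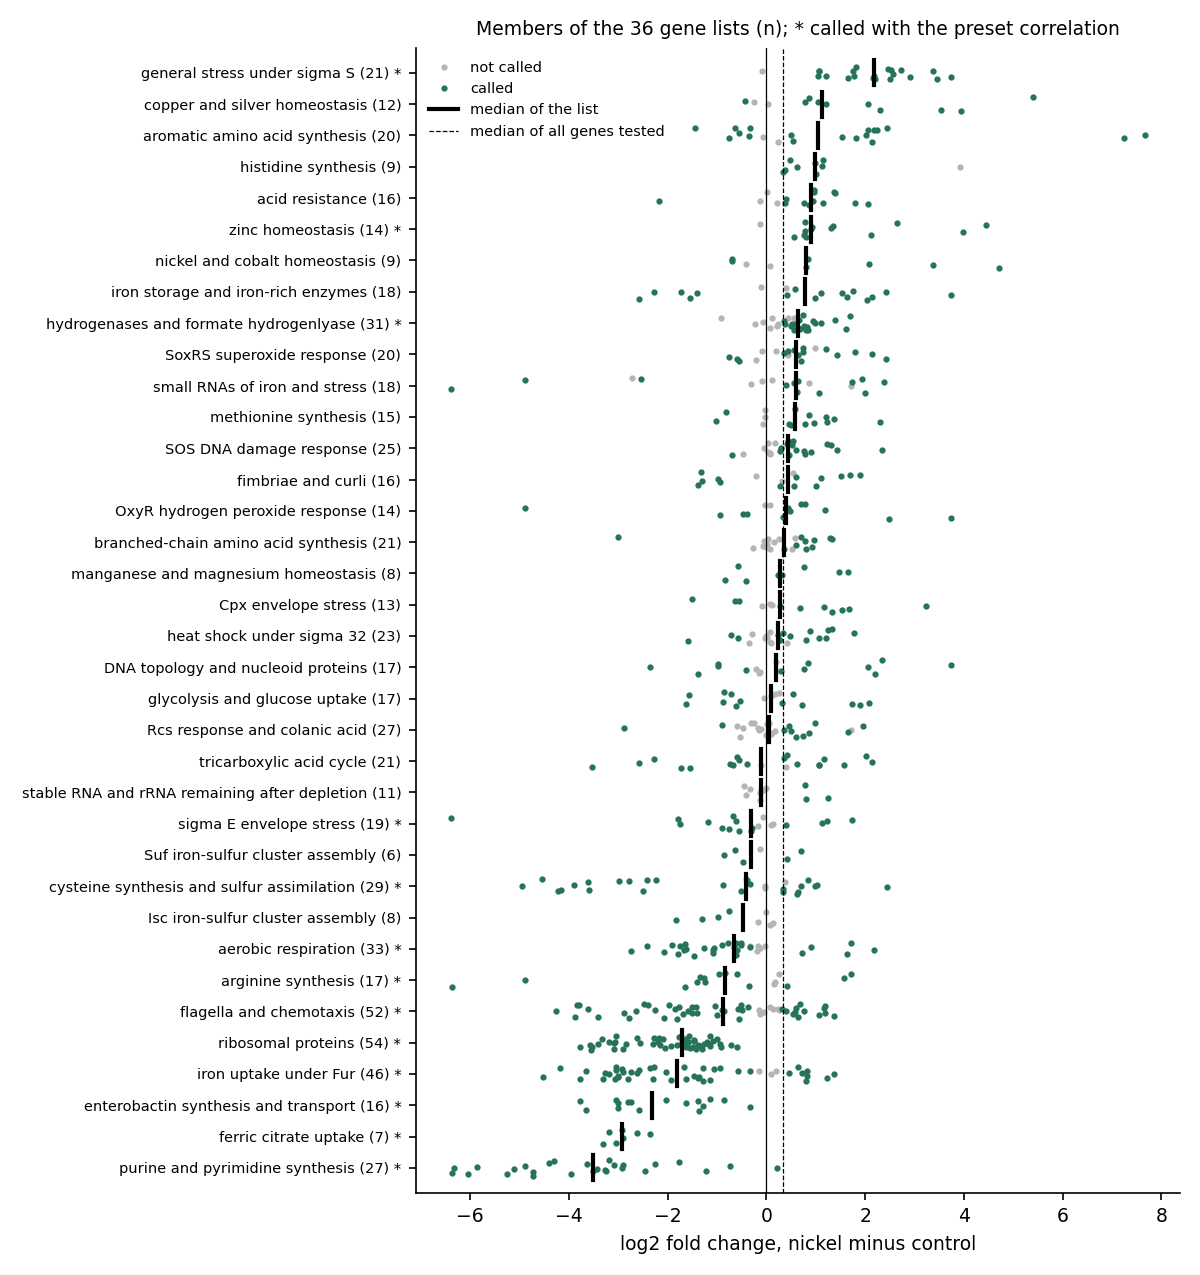
Log2 fold change (nickel minus control) of each tested member of the 36 gene lists, with the number tested in brackets and a star where camera called the list with the preset correlation; thick bars are list medians and the dashed line the median of all genes (0.34). Purine and pyrimidine synthesis had the lowest median (-3.51) and general stress the highest (2.17).

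Nucleotide and ribosome genes fell together. Of 27 genes of purine and pyrimidine synthesis 26 fell and 1 rose (median -3.51; adjusted p = 1.85e-14; adjusted p = 0.413 with an estimated correlation). Besides those above, purD fell by 4.72 and purC by 4.41. The riser, pyrG, which encodes CTP synthetase and was named after its values were seen, changed by 0.21 and passed with FPKM as deposited (adjusted p = 0.0384 by limma). It did not pass under the other scalings (median-of-ratios -0.13, quantile 0.03, equal totals 0.20) or with voom (0.18), without the mean-variance trend (0.21), or without any 1 of the 6 libraries (0.18 to 0.24, adjusted p 0.0542 to 0.0873; 0.0265 to 0.765 over all alternatives). All 54 ribosomal protein genes fell (median -1.70; adjusted p = 1.86e-21; adjusted p = 0.413 with an estimated correlation), under each scaling. Examples were rpmH (-3.77), rplY (-3.20), rplV (-3.09) and rpsA (-2.55).

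Many iron uptake genes also fell. All 16 genes of enterobactin synthesis and transport, the cell's own siderophore, fell (median -2.31; adjusted p = 1.11e-08; adjusted p = 0.413 with an estimated correlation), among them entD (-3.77), fepA (-3.01) and entC (-3.0). All 7 genes of ferric citrate uptake fell (median -2.93; adjusted p = 2.33e-05; adjusted p = 0.413 with an estimated correlation), with fecA at -3.19 and fecC at -3.31. In a wider list of 46 genes under the iron repressor Fur, which holds iron uptake genes and also others such as nrdHIEF and bfd, 35 fell, 8 rose and 3 did not pass (median -1.80; adjusted p = 7.62e-10; adjusted p = 0.450 with an estimated correlation). Adjusted over the list alone, 35 fell and 9 rose. The catecholate receptor genes fiu and cirA fell by 4.53 and 4.18 on the log2 scale. The 8 risers were the ferrous iron transport genes feoA (0.81), feoB (0.72) and feoC (yhgG, 0.83), the ribonucleotide reductase genes nrdH (1.37), nrdI (1.22) and nrdE (0.82), the ferrichrome receptor gene fhuA (0.63) and bfd (0.46); these and cirA were named after their values were seen. The rises of feoC and bfd were lost under median-of-ratios scaling (0.49 and 0.11). That of feoC was also lost without nickel replicate 2 (0.77), and that of bfd without control replicate 2 (0.49), control replicate 3 (0.29), nickel replicate 1 (0.46) or nickel replicate 2 (0.38). The small RNA gene ryhB, which Fur represses, fell by 2.53.

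Iron-using genes went both ways. Of 18 genes for iron storage and iron-rich enzymes, 11 rose and 5 fell (median 0.79; adjusted p = 0.699). The fallers were the succinate dehydrogenase genes sdhC (-2.59), sdhD (-2.28), sdhA (-1.74) and sdhB, and the ferritin gene ftnA, named after its values were seen (-1.41), while ftnB (yecI) rose by 1.62. In the Isc list of iron-sulfur cluster assembly 4 of 8 genes fell, hscB (-1.82), fdx (-1.30), hscA (-0.98) and iscX (-0.76), and 0 rose (adjusted p = 0.0589). The cysteine desulfurase gene iscS and the scaffold gene iscU, named after their values were seen, did not pass (0.00 and 0.07). Without control replicate 3 iscS was -0.10 and iscU -0.03, and under median-of-ratios scaling iscS passed at -0.34 and iscU was -0.28. The Isc list was called under median-of-ratios scaling (adjusted p = 0.0304), with array weights (0.0293) and without control replicate 3 (0.0280), within a range of 0.0280 to 0.117. With an estimated correlation camera did not call it (adjusted p = 0.574). In the Suf list, the alternative assembly system, sufA (0.71) and sufB (0.42) rose, and sufE (-0.86), sufS (-0.63) and sufD (-0.48) fell (adjusted p = 0.494). Under median-of-ratios scaling sufA (0.36) and sufB (0.08) no longer passed, nor did sufB under quantile normalization (0.26). Leaving out 1 library ended the call of sufD (control 1, -0.41; control 2, -0.38; nickel 1, -0.48; nickel 3, -0.40) and of sufB, named after its values were seen (control 2, 0.46; control 3, 0.27; nickel 1, 0.42; nickel 2, 0.34).

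Genes for other metals rose in part. In zinc homeostasis 13 of 14 genes rose (median 0.91; adjusted p = 0.00435; adjusted p = 0.413 with an estimated correlation), including the uptake protein gene znuA (2.64) and the efflux gene fieF (1.34). The zinc exporter gene zntA, named after its values were seen, was -0.13 and did not pass, but passed as a fall under median-of-ratios scaling (-0.45) and quantile normalization (-0.44). In copper and silver homeostasis 9 of 12 genes rose, led by cusC, cusF, cusB (3.54) and cusA (2.30). The oxidase gene cueO fell by 0.43, and the exporter gene copA was -0.25 and did not pass; both were named after their values were seen. The change of copA passed under median-of-ratios scaling (-0.59), quantile normalization (-0.33), array weights (-0.31) and voom (-0.29), and without control replicate 1 (-0.30) or nickel replicate 3 (-0.31). Camera did not call the copper list (adjusted p = 0.0589), but called it under median-of-ratios scaling (0.0304), quantile normalization (0.0387) and rescaling to equal totals (0.0419), and with voom (0.0481), without control replicate 3 (0.0464), nickel replicate 1 (0.0315) or nickel replicate 2 (0.0392), within a range of 0.0304 to 0.108. With an estimated correlation camera did not call the copper list (adjusted p = 0.557). In manganese and magnesium homeostasis 5 of 8 genes rose, phoP (1.65), corA (1.46), mgrB (yobG, 0.76), mntR (0.32) and phoQ (0.24). The 3 fallers were mntH (-0.85), mgtA (-0.57) and mntP (yebN, -0.40), and the list was not called (adjusted p = 0.755). Of these, mntR, phoQ, mntH and mntP were named after their values were seen. The rises of mntR and phoQ were lost under each other scaling, turning negative under median-of-ratios scaling (-0.03 and -0.10) and reaching 0.11 and 0.10 under quantile normalization and 0.30 and 0.23 with equal totals, so that 3 genes rose and 3 fell. Leaving out control 2 (mntR 0.29, phoQ 0.21, mntP -0.32), control 3 (0.28, 0.23, -0.40) or nickel 1 (0.27, 0.21, -0.37) ended these 3 calls; nickel 2 ended those of mntR (0.29) and phoQ (0.23), and nickel 3 that of mntP (-0.32).

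General stress genes under sigma S rose. Of 21 genes 20 rose and 1 did not pass (median 2.17; adjusted p = 0.00104; adjusted p = 0.680 with an estimated correlation), the same count under each scaling. The morphogene bolA rose by 3.45, osmE by 2.92, rpoS, the gene of sigma S itself, by 2.49 and yjbJ by 1.75. The list's median differed between control libraries, at 0.67 in control replicate 1 against -0.31 and -0.34 in the others relative to the control mean, and was 2.10 to 2.23 in nickel. In acid resistance 12 of 16 genes rose, such as hdeA (2.05) and gadW (1.38), and lysP fell by 2.18 (adjusted p = 0.125). Oxidative stress lists were not called. Of 14 OxyR genes 8 rose, among them katG (2.48), dps and oxyR (0.70), and 4 fell, namely fhuF (-0.93), oxyS and, named after their values were seen, hemF (-0.47) and trxB (-0.38; adjusted p of the list = 0.755). Under median-of-ratios scaling 5 OxyR genes rose and 5 fell. The call of trxB was lost without control replicate 3 (-0.29) or nickel replicate 2 (-0.30). In the SoxRS list of 20 genes 12 rose, including acnA (2.13), fpr (1.8), nfo (1.42) and sodB (2.42), which is in the list as a superoxide dismutase gene but is not one that SoxS activates, and 3 fell, namely marR (-0.75), sodA (-0.59) and inaA (-0.56), named after their values were seen (adjusted p of the list = 0.327), against 8 and 5 under median-of-ratios scaling. The regulator gene soxS, also named so, was 0.99 and did not pass (adjusted p = 0.0533 by limma). It passed without nickel replicate 1 (1.41), without both libraries numbered 1 (1.26), with array weights (0.97), with equal totals (0.90), and at 0.99 with the replicate number as a block, with features of at least 200 bases or with at least 10 estimated reads. For soxS the change was smaller without nickel replicate 3 (0.56; adjusted p = 0.114), without control replicate 1 (0.84; adjusted p = 0.138) and under median-of-ratios scaling (0.65; adjusted p = 0.178).

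**Figure D4:**
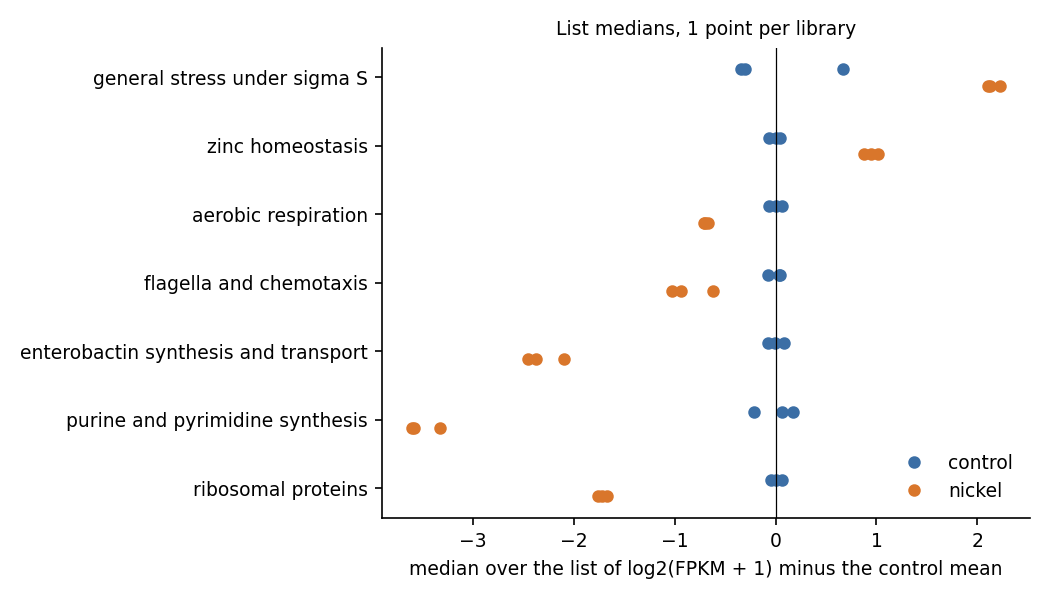
Median over 7 gene lists of log2(FPKM + 1) minus the control mean, with 1 point per library and 3 libraries per group. General stress genes rose above the control libraries, which spread from -0.34 to 0.67, and ribosomal protein genes fell to between -1.76 and -1.67.

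Envelope stress lists went both ways. In the sigma E list 11 of 19 genes fell and 4 rose (median -0.30; adjusted p = 0.0436; adjusted p = 0.547 with an estimated correlation). Fallers included rseC (-1.78), yeaY (-1.75) and rseB (-1.17), and the risers were micA (sraD, 1.74), lptB (yhbG, 1.23), lptA (yhbN, 1.13) and bamE (smpA, 0.40). Both lptA and bamE were named after their values were seen. The rise of bamE was lost under median-of-ratios scaling (0.06) and quantile normalization (0.26), and without control replicate 1 (0.33), nickel replicate 2 (0.34) or nickel replicate 3 (0.34). The sigma E call was lost without control replicate 2 (adjusted p = 0.0554) or nickel replicate 3 (0.0676), and under quantile normalization (0.0528), rescaling to equal totals (0.0559), a mean FPKM of at least 10 (0.0803) or at least 10 estimated reads (0.0602), within a range of 0.0277 to 0.0803. Of 13 Cpx genes 7 rose, including spy (1.67), slt (1.54) and cpxR (1.33), and 3 fell, ppiA (-1.51) and, named after their values were seen, ldtC (ycfS, -0.64) and degP (-0.55); the list was not called (adjusted p = 0.667), and its median of 0.28 was -0.07 under median-of-ratios scaling. The gene cpxP, named in the same way, was 0.08 and did not pass, and turned to -0.27 under median-of-ratios scaling, -0.09 under quantile normalization and -0.04 without nickel replicate 3. Of 27 Rcs and colanic acid genes 9 rose, such as ivy (1.95), and 2 fell, rcsA (-2.87) and, named after its values were seen, rcsF (-0.90; adjusted p of the list = 0.842). Under median-of-ratios scaling 5 Rcs genes rose and 6 fell, and under quantile normalization 4 rose and 7 fell, with the median of 0.05 at -0.24 and -0.23.

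Heat shock and DNA damage lists were not called. Of 23 heat shock genes 11 rose, led by hspQ (yccV, 1.78), clpB (1.33) and clpP (1.21), and 3 fell, namely the chaperone genes groS (-1.59), groL (-0.71) and htpG (-0.58), named after their values were seen (adjusted p of the list = 0.636). Under median-of-ratios scaling 6 heat shock genes rose and 7 fell, and the list's median of 0.23 was -0.12. The fall of htpG was lost without control replicate 2 (-0.44), control replicate 3 (-0.53) or nickel replicate 1 (-0.52). The chaperone gene dnaK, named in the same way, was 0.08 and did not pass; it turned to -0.27 under median-of-ratios scaling, -0.06 under quantile normalization, -0.12 with array weights and -0.18 without control replicate 1. Of 25 SOS genes 16 rose and 1 fell (median 0.44; adjusted p = 0.102), but 7 rose and 6 fell under median-of-ratios scaling and 10 and 2 under quantile normalization. Examples were sbmC (2.34), uvrB (1.43) and umuD (1.30), and the faller was dinF (-0.69). Of the SOS regulators lexA rose by 0.78, while recA was 0.18, did not pass (adjusted p = 0.0662 by limma), turned to -0.17 under median-of-ratios scaling and passed as a rise with array weights (0.17); dinF, lexA and recA were named after their values were seen. In DNA topology and nucleoid proteins 7 of 17 genes rose, including ihfB (2.20) and ihfA (2.07), and 5 fell, fis (-2.35) and, named after their values were seen, stpA (-1.39), topA (-0.98), parE (-0.97) and parC (-0.41). That list's test pointed downward (adjusted p = 0.755), against a median of 0.20 and a mean of 0.36, and under median-of-ratios scaling 5 rose and 8 fell, with a median of -0.14.

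Sulfur and arginine genes were called downward with members on both sides. Of 29 genes for cysteine synthesis and sulfur assimilation 16 fell and 9 rose (median -0.41; adjusted p = 0.00430; adjusted p = 0.481 with an estimated correlation), or 16 and 10 adjusted over the list alone, and 18 and 5 under quantile normalization. The sulfite reductase and sulfate transport genes cysJ (-4.55), cysA (-4.22), cysW (-4.16) and cysU (-3.59) fell, while cysQ, named after its values were seen, rose by 2.43. Of 17 arginine genes 11 fell and 3 rose (median -0.84; adjusted p = 0.0196; adjusted p = 0.450 with an estimated correlation), with argH at -1.25 among the falls. The falls of carA (-6.37) and carB (-4.90), given above, were the largest in this list. The risers were argI (1.71) and, named after their values were seen, argE (1.57) and argR (0.41), whose call was lost under median-of-ratios scaling (0.07) and quantile normalization (0.25).

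Other amino acid lists were not called by camera. In aromatic amino acid synthesis 12 of 20 genes rose and 6 fell (median 1.04; adjusted p = 0.327). Beside aroF and tyrA, tyrB rose by 2.13 and aroL by 1.82, as did pheA (1.54), trpD (2.44) and trpE (2.18), whereas aroG (-0.56) and aroH (-0.63), which encode the isoenzymes of AroF, fell; those last 5 were named after their values were seen. The call of trpE was lost without both libraries numbered 1 (1.8), and its log2 fold change was 2.83 without nickel replicate 2. In histidine synthesis 8 of 9 genes rose (median 0.99; adjusted p = 0.125), or 5 under median-of-ratios scaling, such as hisC (1.15) and hisB (1.0). In methionine synthesis 10 of 15 rose, including mmuM (1.36), mmuP (1.23) and metC (0.87), and metK (-1.02) and metE (-0.82) fell (adjusted p of the list = 0.382); under median-of-ratios scaling 7 rose and 5 fell. Here metR (2.31), which overlaps yigM by 113 bases, metH (0.79) and metE were named after their values were seen. The fall of metE was lost without control replicate 2 (-0.76), control replicate 3 (-0.62), nickel replicate 1 (-0.70) or nickel replicate 2 (-0.80). In branched-chain amino acid synthesis 9 of 21 rose, such as livK (1.33), and ilvC fell by 3.00 (adjusted p of the list = 0.608); under median-of-ratios scaling 6 rose and 3 fell.

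Respiration and motility genes were called downward. Of 33 genes of aerobic respiration 23 fell and 5 rose (median -0.66; adjusted p = 7.61e-06; adjusted p = 0.413 with an estimated correlation). Among those that fell were the ATP synthase genes atpI (-2.73), atpB (-1.79) and atpA (-1.63), the cytochrome bo oxidase gene cyoA (-2.41) and the NADH dehydrogenase gene ndh (-2.08). The risers encode the bd-type oxidases, cydB (2.18), cydA (1.72), cydX (ybgT, 1.63), appB (0.90) and appC (0.72); they and ndh were named after their values were seen. Of 52 genes of flagella and chemotaxis 32 fell and 13 rose (median -0.88; adjusted p = 5.19e-05; adjusted p = 0.557 with an estimated correlation). The master regulator genes flhD and flhC fell by 3.87 and 3.83 on the log2 scale, and fliR by 4.25. The flagellar sigma factor gene fliA (1.19) and the hook-associated genes flgK (1.20) and flgL (1.37) rose. The flagellin gene fliC was 0.25 and did not pass; it was -0.10 under median-of-ratios scaling and passed at 0.87 under quantile normalization and 0.25 with array weights. These 4 were named after their values were seen. In hydrogenases and formate hydrogenlyase, whose hydrogenases contain nickel, 22 of 31 genes rose and 9 did not pass (median 0.64; adjusted p = 0.0328; adjusted p = 0.547 with an estimated correlation). Under median-of-ratios scaling 13 rose and under quantile normalization 14. Examples were hypD (1.70), hycH (1.61) and hycI (1.39). The hydrogenase call was lost without control replicate 2 (adjusted p = 0.0564), under quantile normalization (0.0899) and at a mean FPKM of at least 10 (0.0695), within a range of 0.0132 to 0.0899.

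The remaining lists were not called. In the tricarboxylic acid cycle 9 of 21 genes rose and 10 fell (adjusted p = 0.327); the malate oxidase gene mqo fell by 3.54, and the glyoxylate genes aceB (2.01) and aceA (1.56), named after their values were seen, rose. In glycolysis and glucose uptake 6 of 17 rose and 7 fell (adjusted p = 0.520), with pfkA at 2.07 and the glucose transporter gene ptsG at -1.62; the test pointed downward, against a median of 0.10 that was -0.24 under median-of-ratios scaling and -0.03 under quantile normalization. In fimbriae and curli 8 of 16 rose, such as csgB (1.90) and csgD (1.69), and 5 fell, namely fimG (-1.32), fimF (-1.31) and, named after their values were seen, csgC (-1.38), fimH (-0.97) and fimD (-0.93); the test pointed downward, against a median of 0.43 (adjusted p = 0.842), and 5 rose and 6 fell under median-of-ratios scaling, with 6 each under quantile normalization. Of 18 small RNAs of iron and stress 9 rose and 3 fell, namely ryhB, rybB and oxyS (adjusted p = 0.699), with a median of 0.59 and a mean of -0.16. Among the risers ryeA (1.93) overlaps another small RNA by 121 bases. Of 11 stable RNA features 3 rose, ssrS (1.26), ffs (0.81) and rnpB (0.78), or 2 adjusted over the list alone (adjusted p of the list = 0.842), with a median of -0.10 and a mean of 0.11. The list's control medians lay far apart, at 0.99 in control replicate 1 against -0.084 and -0.66 in the others, with a difference of -0.17 between the groups. Quantile normalization set the change of ssrS to 0. The call of ffs was lost under median-of-ratios scaling (0.46) and without control replicate 1 (0.83), control replicate 3 (0.65), nickel replicate 2 (0.61) or nickel replicate 3 (0.77).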

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

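Of the alternatives, voom on estimated reads, the 200-base minimum, the minimum of 10 estimated reads and leaving out both libraries numbered 1 were chosen after the data were seen. Over the alternatives 2779 to 3477 genes were called (2962 to 3193 with 1 library left out), and 0 genes called in both fits changed direction under any of them. The number changed at least 2-fold was 1203 to 1731. For rcnA the log2 fold change was 4.09 to 4.82 (adjusted p 1.50e-09 to 4.52e-05 by limma). The lists called by camera numbered 11 to 15, but 0 with an estimated correlation. Camera with that correlation weighs how a list's genes vary together, and its residuals come from 6 libraries. Of the 153 genes that the fixed rule names besides rcnA, 144 kept direction and call everywhere. That rule mostly takes genes with the largest changes or the smallest p in these same libraries. The count therefore does not measure how stable the calls of all genes are. Of the 88 named after their values were seen, 23 changed somewhere and 9 changed sign. Of the 36 lists, 26 kept direction and call with the preset correlation. The planned edgeR test was not run, since it needs counts.

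The replicate numbers do not pair the libraries by the correlations of same-numbered deviations (0.029, -0.025 and 0.090), and with the number as a replicate block 3204 genes were called. Among the named genes the block ended the call of pyrG (0.21) and made soxS pass (0.99).

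Signs turned as follows, and the cause was not tested. Under median-of-ratios scaling, which lowers the median of all genes from 0.34 to 0.02, the values were nikD -0.21, pyrG -0.13, dnaK -0.27, mntR -0.028, phoQ -0.10, iscS -0.34, iscU -0.28, recA -0.17, cpxP -0.27 and fliC -0.097. Under quantile normalization they were nikD -0.27, dnaK -0.062, iscS -0.16 and cpxP -0.089, with array weights nikD -0.056, dnaK -0.12 and iscS -0.14, rescaled to equal totals iscS -0.0089, with voom iscS -0.029, and without both libraries numbered 1 nikD -0.18, dnaK -0.092 and iscS -0.018. With 1 library left out the ranges were nikD -0.25 to 0.42, dnaK -0.18 to 0.26, iscS -0.098 to 0.11, iscU -0.035 to 0.17 and cpxP -0.041 to 0.20. For lists the value is the mean log2 fold change minus that of the other genes, and the sign is that of the test. It turned for Rcs at a mean FPKM of at least 10 (0.22), for DNA topology under quantile normalization (0.42), and for stable RNA under median-of-ratios scaling (0.018), with array weights (-0.042) and without both libraries numbered 1 (0.18). With 1 library left out, turns came without control replicate 1, in ranges of 0.026 to 0.19 for heat shock, -0.033 to 0.12 for fimbriae and curli and -0.36 to 0.33 for stable RNA. Depth limits short features most: a single read was worth at least 116.4 FPKM at 76 bases.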

Other observations

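The 8 gene lists of the first paragraphs were chosen after the results were seen, as were the explanations weighed after them and their criteria. The other scalings used there had been planned. All 6 universal stress protein genes tested rose (median 3.11; camera adjusted p = 0.0103 over these 8 lists; adjusted p = 0.391 with an estimated correlation), with uspG at 3.45 and uspA at 2.96. All 7 genes of ribosome hibernation and modulation rose (median 1.94; adjusted p = 0.0258; adjusted p = 0.462 with an estimated correlation), including raiA (yfiA, 3.23), rmf (2.14) and hpf (yhbH, 1.46), whose proteins bind resting ribosomes. Control replicate 1 stood apart here as in general stress, with a median of 0.49 against -0.24 in both others, and the groups differed by 1.99. In the cold shock protein family 7 of 9 genes fell and 1 rose (median -1.53; adjusted p = 0.0103; adjusted p = 0.391 with an estimated correlation), with cspA at -1.38 and the stationary-phase member cspD rising by 2.41. This median lay within the central 95% of random lists matched on expression (-1.63 to 1.08; percentile 5.88). All 4 features of the threonine operon fell (median -2.14; adjusted p = 0.0103; adjusted p = 0.391 with an estimated correlation), thrA by 2.09 and the leader thrL by 0.48 on the log2 scale, beside thrB and thrC. Under quantile normalization 3 of the 4 fell, as thrL no longer passed (-0.22), and thrL was also lost without control replicate 2 (-0.38), control replicate 3 (-0.47), nickel replicate 1 (-0.44) or nickel replicate 3 (-0.47).

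Camera did not call the other 4 lists. Of 23 aminoacyl-tRNA synthetase genes 10 rose and 8 fell (adjusted p = 0.513), or 10 and 9 adjusted over the list alone, with the phenylalanine genes pheT (1.8) and pheS (1.5) rising; under median-of-ratios scaling 3 rose and 12 fell (median -0.31, against 0.03), under quantile normalization 6 and 10 (-0.13), and with equal totals 6 and 7. Of 14 genes for uptake of sugars other than glucose 8 rose and 6 fell (adjusted p = 0.712; 5 and 6 under median-of-ratios scaling, 6 and 6 under quantile normalization), from xylE (3.27) and araF (2.84) to malK (-3.14) and rbsA (-3.21). The genes under the regulator TyrR other than aroF and tyrA (adjusted p = 0.0739) and the genes that the small RNA RyhB represses (adjusted p = 0.281) are weighed in what follows.

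Ribosomal protein genes fell and general stress genes rose together. A scaling by 1 factor per library cannot lower 1 list and raise another, so the opposite directions argue against it as the source of both. With FPKM as deposited 74 of the 75 members were called, and at least 74 under each of the other scalings, in the same directions. That count was largely fixed in advance and adds little. All the scalings are relative, so a change in the total amount of mRNA is not addressed. A few abundant RNAs taking more of the reads would shift all other features by -0.12 (log2; -0.1228), against a ribosomal median of -1.70. The general stress median ranged over 1.005 (log2) between control libraries, against 2.146 between the groups, while the ribosomal median ranged over only 0.11, against -1.73, and was at -0.046 in control replicate 1, the control highest in stress genes. No sampling time was given for the control, so a difference in growth stage between the groups and nickel cannot be told apart.

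The rises of aroF and tyrA were the largest among the called genes. Reads shared with the isoenzyme genes aroG and aroH are argued against, because the higher of these reached 3.098% of the aroF level in nickel. Loss of repression by TyrR may be a source: of 8 other genes under TyrR 6 rose, including the transporter gene aroP (2.72), and aroG fell. Their median lay at percentile 93 of random lists matched on expression, within the central 95%. This explanation thus stays open and cannot be told apart from other causes. The list held genes under TyrR, not only those it represses, and mtr did not pass (0.23). The risers aroL (405629 to 406153) and aroM (406652 to 407329) lie close together, so their rises may not be separate observations.

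Genes under Fur, many of them for iron uptake, fell with a median of -1.80. A trend with expression level is argued against, since the lower 2.5% bound of medians of random lists matched on expression was -0.2142. A response of Fur to nickel or to more iron is a biological candidate explanation that no library here tests. If lower ryhB raised the genes it represses these should rise, but of 10 such genes 4 rose (sodB, acnA, bfr and fumA) and 5 fell (the sdh genes sdhC, sdhD, sdhA and sdhB, and ftnA), with a median of -0.5089. The sdh genes lie side by side on the chromosome, so their falls are not separate observations, and they weigh on the median. As members went both ways, it stays open whether lower ryhB raised the genes it represses. Neither outcome could show why the genes under Fur fell, since ryhB is itself repressed by Fur.

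With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 3244 genes and the highest other split 1 gene, so that only the real split gave as many. For lists called by camera with the preset correlation the real split called 13 and the highest other 18. At least as many were called in 6 of the 10 splits, the real one included. Every other split mixes control and nickel libraries in both of its groups. It thus keeps part of the difference between the conditions and widens the spread within its groups. For these reasons the other splits give no level to be met by chance, for genes or for lists.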
